A study of Mus musculus with 12 samples.

How the data were processed

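Total RNA from sorted bone marrow cells, labelled as wild-type mouse HSPC, was extracted with a PicoPure kit and made into libraries with standard Illumina protocols, per the labels' protocols. The design text gives a transfection with control miR, miR184 or miR499 and extraction 2 days later. Groups and replicate numbers were taken from the sample titles. The 12 libraries fell into 3 groups, 6 with control miR, 3 with miR184 and 3 with miR499.

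The authors deposited 2 tables, one per miRNA, each with 48709 genes, 3 treated libraries and 3 control libraries of its own. Values are RPKM, per the file headers, so the authors divided the reads of each gene by its length and by the library's total. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation and the use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes, such as histone, ribosomal RNA and interferon-induced families, may be split between entries. Gene symbols, positions, 3' UTRs and coding sequences came from GENCODE M21 on GRCm38, the assembly of mm10, whose symbols match 96.3% of the genes above 0. The number of columns of per-sample values left unused was 0.

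Reads were recovered from the RPKM values, because within a gene the values of different libraries are whole multiples of a step set by the gene's length and the library's total. For all 21134 genes above 0 in any library, 100% of the values above 0 came out as whole reads within 0.01 reads. The recovered length equalled the exon length in GENCODE M21 for 14462 genes. The library totals were 46601798, 45570240 and 43413665 reads for controls 1 to 3, 43122681, 39318912 and 43076576 for miR184 1 to 3, 44750230, 45552326 and 31990355 for controls 4 to 6, and 42984086, 44273264 and 41793603 for miR499 1 to 3. A count of 0 allows up to 3 reads, a limit that covers counting error only. Pairs of replicates differed by far more than counting noise, with a chi-square per degree of freedom of 9.41 to 397, so no library was treated as a second deposit of another. This does not show that they are separate biological samples.

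Each miRNA was tested against the 3 controls of its own table with limma (version 3.58.1, R 4.3.3), with an intensity trend in the empirical Bayes step, on log2(RPKM + 1). A gene entered if its mean RPKM over the 6 libraries was at least 1, and passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Had the tables held counts, a count model would have been used; as they hold RPKM, the form of the test fixed for that case was used. An exact test of 3 against 3 libraries cannot go below p = 0.1, so single genes rest on limma's pooled spread. All tests are two-sided.

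A total of 27 gene lists of blood lineages, cell cycle, stress and antiviral responses, metabolism and published miRNA targets, fixed before the data were examined, were tested with camera of limma at its preset correlation of 0.01 where at least 5 members were tested. Camera with an estimated correlation and fry of limma stood beside it. Genes with an 8mer, 7mer-m8 or 7mer-A1 site, from seed bases 2 to 8, in the longest annotated 3' UTR were compared with genes without one by camera, with the other arm, the other miRNA and permuted 7mers as controls. The difference between the 2 miRNAs was tested by a z test per gene on the 2 changes and their standard errors, with the same adjustment.

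The genes named were chosen by a rule written before the data were examined. As fewer than 5 genes passed in either comparison, these are the 5 higher and 5 lower genes with the smallest p at a level of at least 5 RPKM, the measured published targets, Mir184, Mir499 and Myh7b, up to 2 members of each list with the smallest p, and the 5 smallest adjusted p in each direction for the difference, of which 1 gene is not reported here. The entries Rn18s-rs5, Lars2 and Malat1 and the genes that passed without control 1 or with the replicate block were added after their values were seen.

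The test was run first on simulated data with 200 changed genes, 4 of which (miR184) and 10 (miR499) lay under the filter and counted as missed. It called 7 unchanged genes in the simulated miR184 comparison and 0 in that of miR499, and 0 genes in either when nothing was changed. Alternatives covered the scaling, the filter, the pseudocount, limma voom on recovered reads, all 12 libraries in one fit, a replicate block, each library left out in turn, and the site definition. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of reads and the figures.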

Results

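Hematopoietic stem and progenitor cells (HSPC), the bone marrow cells from which all blood lineages arise, were taken from wild-type mice and transfected with miR184, miR499 or a control miRNA (control miR), and their RNA was sequenced 2 days later. The study's title places these miRNAs in the proliferation and differentiation of HSPC. The 12 libraries comprised 3 with miR184, 3 with miR499 and 6 with control miR. Controls 1 to 3 stood in the deposited table of miR184 and controls 4 to 6 in that of miR499, so each miRNA was compared with the controls of its own table. Library totals recovered from the RPKM values (reads per kilobase of gene, scaled to the library's total) ran from 31990355 reads in control 6 to 46601798 in control 1. At these totals, 3 reads in a gene of 2000 bases correspond to an RPKM of 0.0322 to 0.0469. The labels do not say that the replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

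One library in each treated group stood apart from the other libraries of its table. The library miR184 3 listed 13675 genes above 0, against 16702 to 17136 in the other 5 libraries of its table. It carried the first principal component of that table, which held 61.2% of the variance. The library miR499 3 carried the first component of the other table, with 76.1% of the variance. Its log2(RPKM + 1) values correlated on average at 0.947 with the other libraries of its own table and at 0.959 with those of the miR184 table, while for the other 11 libraries the mean correlation was higher within their own table. Its RPKM values summed to 391857, against 465018 to 483368 in the other 5 libraries. The counts of genes and lists that passed are also given without the library in question, a choice made after seeing the data.

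**Figure D1:**
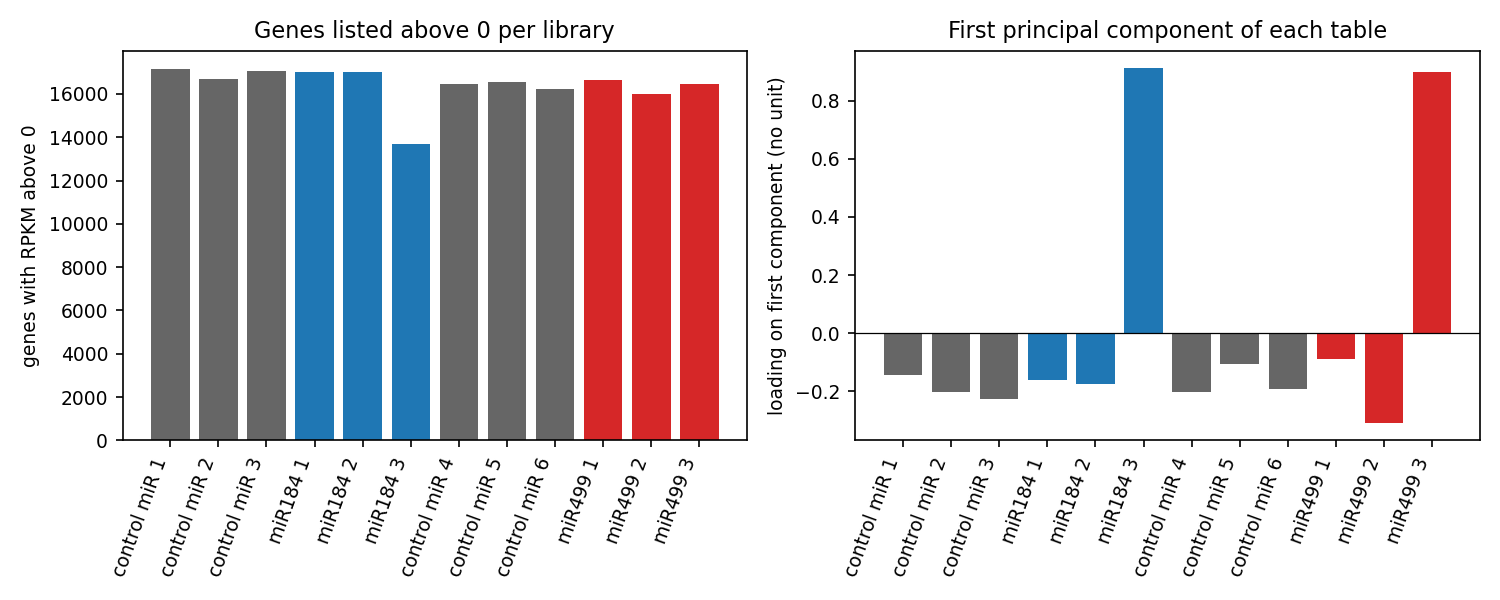
Left, number of genes with an RPKM above 0 in each of the 12 libraries; right, loading (no unit) of each library on the first principal component of its own table. Grey bars are control miR, blue bars miR184 and red bars miR499; miR184 3 lists 13675 genes, and miR184 3 and miR499 3 lie on the other side of 0 from the remaining libraries of their tables.

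The transfected miRNAs were looked for first among the listed genes. Mir184 (chromosome 9, 89802260 to 89802328, minus strand) and Mir499 (chromosome 2, 155622880 to 155622958, plus strand) were listed at 0 in all 12 libraries. These entries are short precursor genes, and a transfected mature miRNA need not be seen in them, so they do not check the labels. Myh7b, the myosin gene that hosts Mir499 in an intron, reached at most 0.0385 RPKM in any library.

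To find out how miR184 altered HSPC transcripts, its 3 libraries were compared with controls 1 to 3. No gene passed the test, and the values below describe the smallest p-values at a level of at least 5 RPKM. Gpnmb, a membrane glycoprotein of the macrophage lineage (chromosome 6, 49036546 to 49070929), stood at 24.1 ± 4.21 RPKM in controls and 66.6 ± 10.2 with miR184 (SD, n = 3 each), a log2 change of 1.43 ± 0.15 (SE). Lmnb1, which encodes the nuclear lamina protein lamin B1 (chromosome 18, 56707813 to 56753424), stood at 13.7 ± 2.07 and 31.0 ± 3.62 RPKM, a log2 change of 1.13 ± 0.12. The galectin gene Lgals3 stood at 111 ± 5.42 and 167 ± 15.1 RPKM. Pld3 and Isoc1 completed the higher genes, with log2 changes of 0.49 ± 0.08 and 0.57 ± 0.09. Among lower genes, Nfkbia, which encodes the inhibitor IκBα of NF-kappaB, stood at 50.9 ± 8.53 RPKM in controls and 36.7 ± 0.293 with miR184, a log2 change of -0.45 ± 0.11. The other lower genes were I830127L07Rik at -0.25 ± 0.05, Nrbf2 at -0.27 ± 0.07, the histone gene Hist1h2ae at -0.69 ± 0.18 and the chemokine receptor gene Cx3cr1 at -0.43 ± 0.12. In all 10 of these genes the 3 miR184 libraries lay on one side of the 3 controls.

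By limma, 0 of 10372 tested genes passed an adjusted p of 0.05. Of these genes, 475 had an unadjusted p under 0.05, and the smallest adjusted p was 0.118, a value that Gpnmb and Lmnb1 had. With limma voom on the recovered reads, 0 genes passed and 489 had an unadjusted p under 0.05. The groups did not overlap in 1214 genes (11.7%), where chance gives 10%. The 95% interval of a gene with the median standard error reached 0.24 log2 units to either side. Without miR184 3, 0 genes passed, 722 had an unadjusted p under 0.05, and the smallest adjusted p by limma was 0.056, a value that Gpnmb and Lgals3 had. Without control 1, 2 genes passed by limma at an adjusted p of 0.033, both higher with miR184. These were Igfbp7, with a log2 change of 1.90 ± 0.12, and the platelet glycoprotein gene Gp1bb, with 1.58 ± 0.11. With a replicate block, which joined libraries by title number, Gpnmb and Cdkn1c passed (adjusted p = 0.038, limma). The descriptions give different numbers to the libraries joined as replicates 2 and 3, so this pairing is uncertain. With array weights, chosen after seeing the data, 167 genes passed, 160 higher and 7 lower, where miR184 3 had a weight of 0.118. In simulated data the main test recovered 75% of genes changed 2-fold and 90% of those changed 4-fold. The simulation took genes as independent and the spread as equal in every library. In the real table miR184 3 stood apart, so these shares need not hold there.

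**Figure D2:**
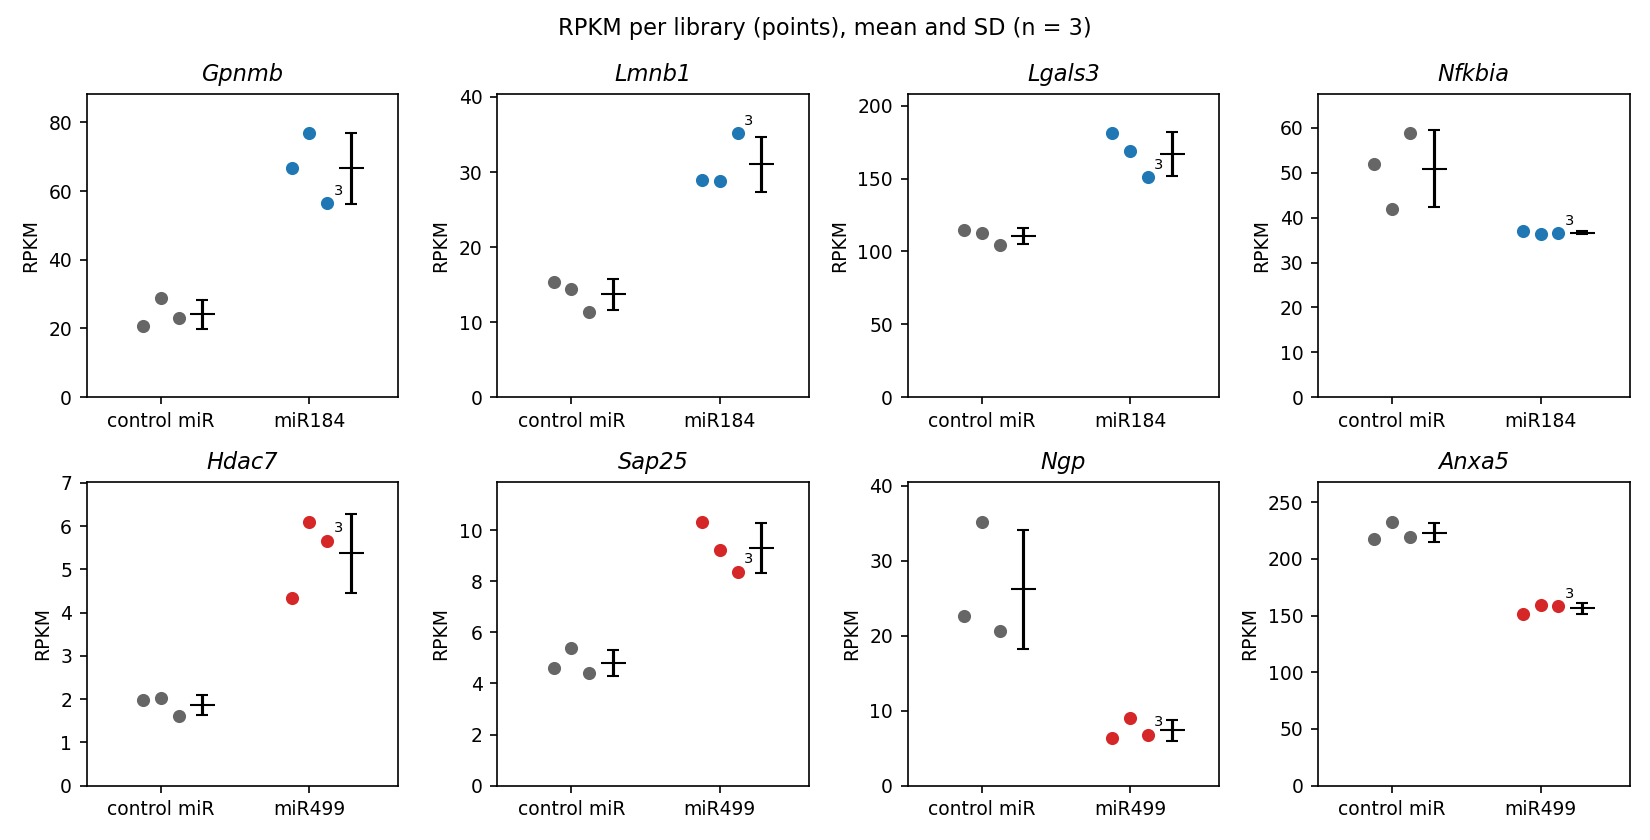
RPKM of 4 genes of the miR184 comparison (top) and 4 of the miR499 comparison (bottom) in each library. Points are libraries, with the number 3 beside replicate 3 of the treated group; horizontal lines with bars are the mean ± SD (n = 3 per group). The treated libraries lie wholly above the controls for Gpnmb, Lmnb1, Lgals3, Hdac7 and Sap25, and wholly below them for Nfkbia, Ngp and Anxa5, yet no gene passed the test over all genes.

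Measured members of the published miR-184 target list were close to their control levels. Akt2, a kinase gene of the insulin pathway, stood at 14.0 ± 0.132 RPKM in controls and 14.2 ± 1.10 with miR184 (SD, n = 3 each). The oncogene Myc stood at 128 ± 2.06 and 126 ± 6.89 RPKM. The anti-apoptotic gene Bcl2 stood at 20.1 ± 0.672 and 19.6 ± 0.482 RPKM. Log2 changes were -0.15 ± 0.13 for Ago2, -0.13 ± 0.13 for Slc25a22 and 0.01 ± 0.15 for Crtc1. Without miR184 3 they were -0.05 ± 0.09 for Ago2 and 0.17 ± 0.08 for Crtc1, and none of the 6 passed. For all 6 targets the groups overlapped, and the camera test of the list gave an adjusted p of 0.370.

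Groups of genes fixed beforehand showed small shifts with miR184, some of which rested on 1 library. Interferon-stimulated genes, the antiviral genes that cells switch on after sensing foreign RNA, were lower in 33 of 34 tested members, with a median log2 change of -0.35. Their mean level was 4.02, 4.56 and 5.35 log2 units in controls 1 to 3 and 4.05 to 4.63 with miR184. Without control 3 the median was -0.03 and 18 of 34 members were lower, while it was -0.61 without control 1 and -0.21 without miR184 1. Genes of cholesterol synthesis were lower in 16 of 20 members (median -0.09), among them Msmo1 at -0.25 ± 0.08 and Stard4 at -0.19 ± 0.08. NF-kappaB and inflammatory genes were lower in 14 of 17 members (median -0.19), with Nfkbia given above and Tnfaip3 at -0.45 ± 0.13. Without control 3 their median was -0.0017 and 9 of 17 members were lower. G2 and M phase genes were lower in 18 of 26 members (median -0.06), and all 13 mitochondrially encoded genes were lower (median -0.05). Dendritic cell genes were higher in 6 of 10 members (median 0.14, with 0.07 without control 2 and 0.21 without control 1), with the antigen-presentation genes H2-Aa at 35.1 ± 3.70 RPKM in controls and 49.4 ± 4.56 with miR184, and H2-Ab1 with a log2 change of 0.53 ± 0.11. Megakaryocyte genes were higher in 13 of 15 members (median 0.07), with Gp1bb at 2.77 ± 1.49 and 7.72 ± 0.330 RPKM. Glycolysis genes were higher in 14 of 18 members (median 0.05). The median was -0.01 without control 1 for mitochondrially encoded genes, -0.03 without miR184 2 for G2 and M phase genes, and 0.04 without miR184 1 for megakaryocyte genes.

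These 8 of 25 tested lists passed camera of limma with its preset correlation of 0.01, 3 upwards and 5 downwards. The adjusted p was 1.5e-05 for interferon-stimulated genes, 0.00038 for cholesterol synthesis, 0.0070 for both G2 and M phase and dendritic cell genes, 0.010 for NF-kappaB, 0.019 for megakaryocyte, 0.030 for mitochondrially encoded and 0.048 for glycolysis genes. None of the 8 passed with an estimated correlation, where each list had an adjusted p = 0.618 with an estimated correlation, and other groupings of the same 6 libraries gave up to 7 lists. Only cholesterol synthesis and dendritic cell genes passed whichever single library was left out. The calls of interferon-stimulated genes were lost without control 3. Those of NF-kappaB genes were lost without control 3, miR184 1 or miR184 2, and those of G2 and M phase genes without control 1 or miR184 2. Megakaryocyte genes lost theirs without control 2 or miR184 1, and glycolysis genes with median-ratio scaling or without any library but control 2. Mitochondrially encoded genes lost theirs without control 1 or any 1 miR184 library. The number of lists that passed was 5 without control 3 and 4 without miR184 1.

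Lineage genes outside these lists showed both directions with miR184. Neutrophil genes were higher in 12 of 17 members (median 0.09), HSC and multipotent progenitor genes in 11 of 18 (median 0.04), erythroid genes in 5 of 8 (median 0.08) and monocyte and macrophage genes in 5 of 16 (median -0.08). Without miR184 3 these medians were 0.24, 0.01, -0.03 and -0.05 in the same order. Without control 3 the neutrophil median was -0.05 and the monocyte median -0.03, and without miR184 1 the neutrophil median was -0.01. Cdkn1c, a cell cycle inhibitor gene linked to quiescence of stem cells, stood at 4.14 ± 1.43 RPKM in controls and 15.5 ± 5.67 with miR184, a log2 change of 1.65 ± 0.32. Odc1, which encodes the first enzyme of polyamine synthesis, had a log2 change of 1.05 ± 0.22. Chaf1a, a chromatin assembly gene of S phase, stood at 22.7 ± 0.915 and 31.7 ± 3.15 RPKM, and the macrophage gene Cd68 at 52.8 ± 3.23 and 69.1 ± 3.46. As lists, cell cycle inhibitor and quiescence genes were higher in 6 of 14 members (median -0.02) and S phase genes in 12 of 26 (median -0.0015). The myeloid transcription factor gene Cebpa had a log2 change of 0.79 ± 0.25, with overlapping groups. The remaining 17 tested lists had adjusted p-values of 0.063 to 0.732 in camera of limma. Neutrophil genes passed upwards without miR184 3 (adjusted p = 0.00055, camera of limma; adjusted p = 0.774 with an estimated correlation) or without control 1. Mast cell, basophil and eosinophil genes did so without control 1, control 2, miR184 2 or miR184 3. Monocyte genes (down) and calcineurin genes (up) passed without control 1, and MYC and ribosome biogenesis genes (up) without miR184 2. With an estimated correlation no list passed whichever single library was left out, and the smallest adjusted p in camera of limma was 0.590, without control 2. Across the lists 12 members in 8 lists passed when adjusted over the list alone, and 0 passed over all genes tested. The median, mean and test of a list differed in sign in 4 lists, none of them among the 8 that passed. Lists of T and NK lymphoid genes and of stromal and endothelial genes had fewer than 5 tested members and were not tested.

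**Figure D3:**
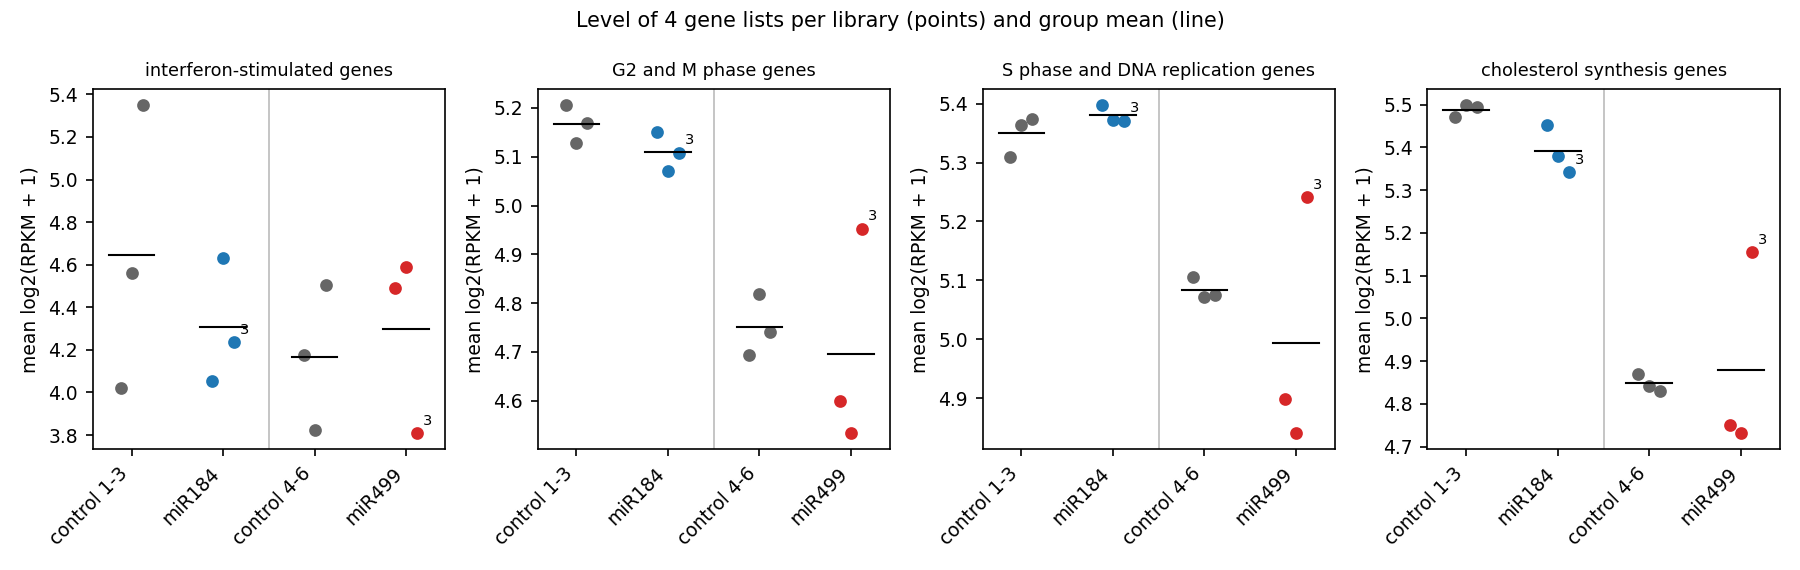
Mean log2(RPKM + 1) over the tested members of 4 gene lists in each library (points; the number 3 marks replicate 3 of a treated group) with the group mean (line). Levels of the left and right of each panel come from tables deposited separately. Interferon-stimulated genes span 4.02 to 5.35 in controls 1 to 3, and miR499 3 lies above the other miR499 libraries in S phase, G2 and M phase and cholesterol synthesis genes.

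Transcripts with seed sites of miR-184-3p, taken as the main arm, did not move as a set with miR184. Genes with a site of miR-184-3p in the 3' UTR (TCCGTCCA as the 8mer, TCCGTCC or CCGTCCA as 7mers) numbered 472, against 9194 genes with an annotated 3' UTR and no site. Their mean log2 changes were 0.01 in both sets, a difference of -0.0015 ± 0.0044 (SE over libraries). The unadjusted p by camera of limma was 0.933 and the adjusted p over 16 seed tests was also 0.933. Of 59 other 7mers made by permuting the seed, 7 gave a difference as low. The 66 genes with the 8mer differed by 0.03 in the upward direction (adjusted p = 0.264, camera of limma). With the trend on 3' UTR length and GC content removed, the difference of the 472 site genes was -0.0132 (unadjusted p = 0.438, camera of limma). A shift of -0.1 added evenly to the site genes of these libraries gave -0.10, a size that the added shift itself sets. Its p was 2.3e-13 by camera of limma at the preset correlation. An uneven effect on part of the site genes was not simulated.

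With miR499, compared with controls 4 to 6, again no gene passed while all 6 libraries were kept. Hdac7, which encodes a class IIa histone deacetylase (chromosome 15, 97792664 to 97844502), stood at 1.87 ± 0.230 RPKM in controls and 5.37 ± 0.913 with miR499 (SD, n = 3 each), a log2 change of 1.14 ± 0.17 (SE). Sap25, Smco4 and Slc25a28 were higher by 0.83 ± 0.15, 0.75 ± 0.16 and 0.78 ± 0.17. The noncoding RNA gene Gm26917 (chromosome 17, 39843013 to 39846341) stood at 43.2 ± 3.42 and 111 ± 33.2 RPKM. The ribosomal RNA entry Rn18s-rs5, a sign of leftover ribosomal RNA, ranged over 26.4 to 31.0 in controls and 43.6 to 114 with miR499. Both entries ranked the 6 libraries alike, with miR499 3 highest at 141 and 114 RPKM. The change of Gm26917 therefore cannot be told apart from leftover ribosomal RNA. Ngp, a granule protein gene of neutrophil precursors, stood at 26.2 ± 7.89 RPKM in controls and 7.37 ± 1.41 with miR499, a log2 change of -1.67 ± 0.23. The membrane-binding gene Anxa5 stood at 223 ± 8.46 and 156 ± 4.62 RPKM, and Hmgb3, a chromatin protein gene of progenitor cells, at 157 ± 6.58 and 110 ± 5.22. Sdcbp and Bcap29 had log2 changes of -0.52 ± 0.11 and -0.48 ± 0.10.

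By limma, 0 of 9815 tested genes passed, 992 had an unadjusted p under 0.05, and the smallest adjusted p was 0.491, shared by all 10 genes named here. With limma voom on the recovered reads 0 genes passed and 967 had an unadjusted p under 0.05. The groups did not overlap in 2374 genes (24.2%), where chance gives 10%. In simulated data 32% of genes changed 2-fold and 72% of those changed 4-fold were recovered, again with independent genes and an equal spread in every library. Without miR499 3, 1681 genes passed by limma, 341 higher and 1340 lower with miR499. With median-ratio scaling added, chosen after seeing the data, 1230 passed, 586 higher and 644 lower, and 985 genes were shared in the same direction. The descriptions of controls 4 to 6 carry a mark that 0 miR499 libraries carry, so a batch behind it holds 1 group only and gives no within-batch value. All 10 genes named above passed in both of these fits, among them Hdac7 with a log2 change of 1.11 ± 0.14 (adjusted p = 0.0094, limma) and Ngp with -1.63 ± 0.21 (adjusted p = 0.0094, limma). These genes were picked for their smallest p in libraries that both fits reuse, so their passing is no separate support.

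Published miR-499 targets showed both directions. Of 9 tested members 6 were higher and 3 lower, with a median log2 change of 0.18, and the camera test of the list gave an adjusted p of 0.265. Pdcd4, a tumour suppressor gene often used as a miR-499 target, stood at 82.8 ± 7.07 RPKM in controls and 89.3 ± 30.3 with miR499 (SD, n = 3 each). Without miR499 3 its log2 change was 0.36 ± 0.09 (adjusted p = 0.029, limma), and Fnip1 was higher by 0.44 ± 0.12 (adjusted p = 0.044, limma). Hbp1 fell in that fit by 0.48 ± 0.09 on the log2 scale (adjusted p = 0.012, limma). The log2 changes with all libraries were 0.20 ± 0.13 for Ppp3ca, 0.42 ± 0.20 for Ppp3cb, 0.18 ± 0.13 for Ptbp3, 0.33 ± 0.17 for Pacs2, -0.0015 ± 0.23 for Ets1 and -0.13 ± 0.25 for Cdkn1a. None of these 6 passed with or without miR499 3. Without that library Cdkn1a stood at 0.15 ± 0.11, Ets1 at -0.25 ± 0.10 and Pacs2 at 0.16 ± 0.10.

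Antiviral, cell cycle and lineage genes were compared in the same way with miR499. Interferon-stimulated genes were higher in 20 of 34 members, with Stat2 at 2.64 ± 0.564 RPKM in controls and 6.09 ± 2.62 with miR499 and Oas3 at 2.38 ± 0.380 and 5.90 ± 3.23 (SD, n = 3 each). S phase genes were lower in 16 of 26 members, with Ccne2 at 16.7 ± 0.366 and 11.5 ± 0.901 RPKM and Rrm2 at 160 ± 4.65 and 127 ± 14.7. G2 and M phase genes were lower in 15 of 26 members and higher in 11 (median -0.10). Ccnb1, which encodes the cyclin that drives entry into mitosis, stood at 82.6 ± 3.89 and 61.5 ± 7.27 RPKM. The neutrophil list, which holds Ngp, was higher in 12 of 17 members, HSC and multipotent progenitor genes in 9 of 15, monocyte and macrophage genes in 6 of 15 and erythroid genes in 6 of 10. Their medians were 0.12, 0.13, -0.05 and 0.10 with all libraries, and 0.01, 0.03, -0.10 and -0.10 without miR499 3, where 10, 9, 5 and 3 members were higher. Small RNA pathway genes were higher in 12 of 16 members, with Ago1 at 1.23 ± 0.256 and 2.10 ± 0.319 RPKM. With all 6 libraries the 25 tested lists had adjusted p-values of 0.130 to 0.864 in camera of limma, so 0 passed, 5 had an unadjusted p under 0.05, and 0 passed by fry of limma. Across the lists, 1 member (Ngp) passed when adjusted over the list alone and 0 passed over all genes tested. The median, mean and test of a list differed in sign in 4 lists.

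Without miR499 3, with 2 miR499 libraries against 3 controls, 6 lists passed camera of limma with the preset correlation. All 6 calls were lost with an estimated correlation. Interferon-stimulated genes rose, with a median log2 change of 0.37 and 9 members that passed, all upwards (adjusted p = 1.3e-06), and mitochondrially encoded genes rose with a median of 0.20 (adjusted p = 0.00077). Both had an adjusted p = 0.686 with an estimated correlation. The mean level of the interferon-stimulated list was 4.17, 3.82 and 4.51 log2 units in controls 4 to 6, and 4.49 and 4.59 in miR499 1 and 2. The library miR499 1 thus lay below control 6, and the left-out miR499 3 was the lowest of all at 3.81. The mean level of the mitochondrially encoded list was 10.68, 10.73 and 10.77 in controls 4 to 6, and 11.15 and 10.83 in miR499 1 and 2. The rise was thus largest in miR499 1, and the left-out miR499 3, at 10.69, lay within the range of the controls. S phase genes fell, with a median of -0.26 and 11 members that passed, all lower (adjusted p = 0.0074), and G2 and M phase genes fell, with a median of -0.15, 9 members lower and 1 higher (adjusted p = 0.033), where each also had an adjusted p = 0.686 with an estimated correlation. Immediate-early genes fell, with a median of -0.30 (adjusted p = 0.033, and adjusted p = 0.686 with an estimated correlation), among them Fos with a log2 change of -0.63 ± 0.10. Unfolded protein and integrated stress response genes fell, with a median of -0.20 (adjusted p = 0.040, and adjusted p = 0.686 with an estimated correlation), among them Pdia4 with -0.70 ± 0.07. The left-out miR499 3 went the other way, above all 3 controls, in each of these falling lists. Its mean level was 5.24 log2 units for S phase genes, against 5.07 to 5.11 in the controls. For G2 and M phase genes it was 4.95 against 4.69 to 4.82. For immediate-early genes it was 3.84 against 3.34 to 3.44, and for stress response genes 5.56 against 5.38 to 5.43. With median-ratio scaling the call of the stress response list was lost as well (adjusted p = 0.071, camera of limma), and the other 5 were still called. In that fit 6 S phase members passed, all lower (median of the list -0.18), and 6 G2 and M phase members passed lower and 2 higher (median -0.08). There 9 interferon-stimulated genes passed, all higher (median 0.44), and 4 mitochondrially encoded genes, all higher (median 0.28), against 2 of the latter before scaling. Rn18s-rs5 and Gm26917 were also higher in miR499 1 and 2 than in all 3 controls, at 63.1 and 43.6 RPKM for the former and 117 and 75.1 for the latter. Leaving out control 6 in place of miR499 3 gave 1 list, interferon-stimulated genes, upwards, and none with an estimated correlation, where the smallest adjusted p of any list was 0.798.

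Genes with a site of miR-499-5p in the 3' UTR (AGTCTTAA as the 8mer, AGTCTTA or GTCTTAA as 7mers) were not lower with miR499. The 1545 genes with a site had a mean log2 change of 0.07, against 0.03 in 7554 genes without one, a difference of 0.03 ± 0.02 (SE over libraries). The unadjusted p by camera of limma was 0.058 and the adjusted p over 16 seed tests 0.233. With the trend on 3' UTR length and GC content removed, the difference was -0.0026. Without miR499 2 it was 0.05, with an unadjusted p under 0.05 by camera of limma, and without miR499 1 it was 0.02. Sites of the untransfected miR-184-3p gave a larger difference in these libraries, 0.11 in 442 genes (adjusted p = 0.0062, camera of limma; unadjusted p = 0.509 with an estimated correlation). It was 0.05 without miR499 3, where its unadjusted p was above 0.05, and 0.0067 with the trend removed. The 60 genes with its 8mer differed by 0.18 (adjusted p = 0.0046, camera of limma; unadjusted p = 0.274 with an estimated correlation). That difference was 0.12 without miR499 3, where its unadjusted p was still under 0.05, and 0.07 with the trend removed, where it was above 0.05. Of 100 permuted 7mers, 64 gave a difference as low as that of miR-499-5p. A shift of -0.1 added evenly to the site genes of these libraries gave -0.07 with a p of 0.080 (camera of limma). Its size is set by the added shift and the difference of 0.03 already there. A shift of -0.2 gave -0.17 with a p of 1.1e-07 (camera of limma). In 20 simulated comparisons with independent genes, a shift of -0.1 was found in 100%.

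**Figure D4:**
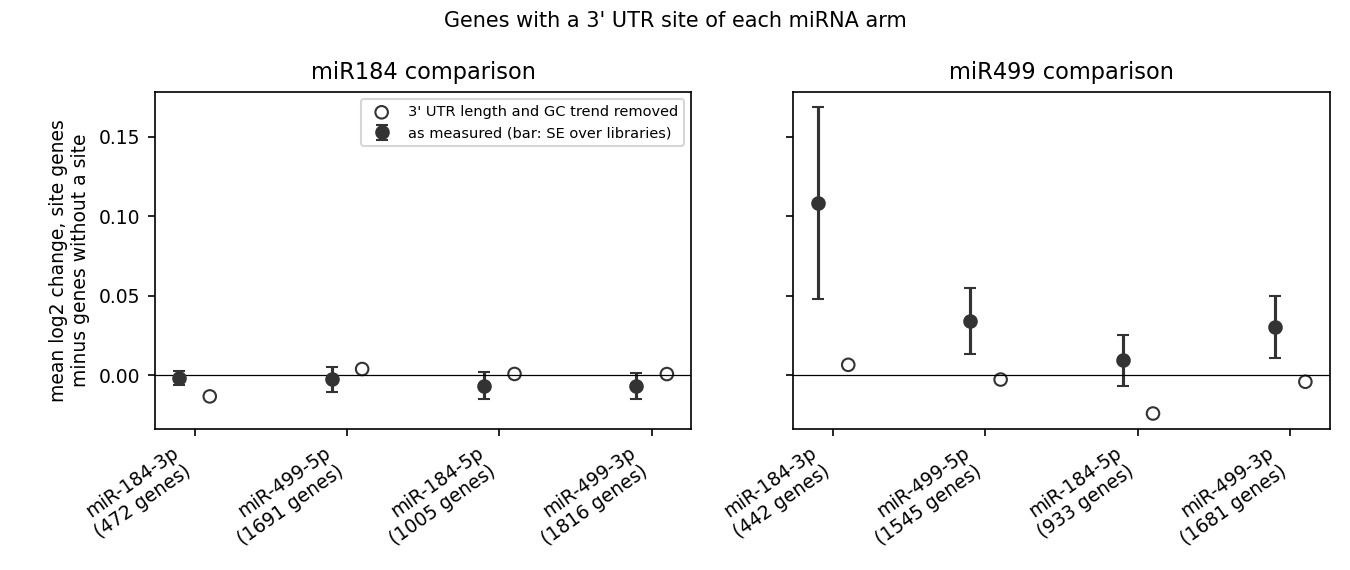
Mean log2 change of genes with a 3' UTR site minus that of genes without one (y axis, log2 units) for 4 miRNA arms, in the miR184 comparison (left) and the miR499 comparison (right), with the number of site genes under each arm. Filled points are the values as measured with the SE over libraries, and open points the values after the trend on 3' UTR length and GC content was removed. The sites of miR-184-3p give -0.0015 with miR184 and 0.11 with miR499.

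To compare the effects of the 2 miRNAs directly, the difference between their log2 changes was tested for 9566 genes measured in both tables. Igfbp7, which encodes a secreted insulin-like growth factor binding protein (chromosome 5, 77349240 to 77408041), had the smallest p, with log2 changes of 1.54 with miR184 and -0.20 with miR499. Its RPKM was 2.25 ± 1.51 in controls 1 to 3 and 7.86 ± 0.359 with miR184, and 20.3 ± 0.580 in controls 4 to 6 and 17.6 ± 2.69 with miR499 (SD, n = 3 each), in tables that were deposited separately. Eed, a component of the Polycomb complex PRC2, differed by 0.69 ± 0.13 (SE), Klhdc2 by 0.86 ± 0.18 and Bag1 by 1.11 ± 0.24, all towards miR184. In the other direction Hdac7 differed by -0.94 ± 0.21, the dynein gene Dync1h1 by -0.83 ± 0.19, Mapk1ip1l by -0.61 ± 0.14 and the hematopoietic transcription factor genes Lyl1 and Runx3 by -0.80 ± 0.19 and -0.70 ± 0.17. In the z test on the 2 limma fits 63 genes differed, 50 with a higher change under miR184 and 13 with a lower one. Its adjusted p ran from 0.00033 for Igfbp7 to 0.017 for Runx3 among the genes named. This z test takes the standard errors as exact, although each fit had only 4 residual degrees of freedom, with a prior of 3.2 (miR184) and 2.9 (miR499). Its p-values are therefore too small, and the 63 genes are not a firm count.

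These calls were lost in another test of the same difference. One limma fit of all 12 libraries with a contrast, chosen after seeing the data, gave 0 genes, with 911 at an unadjusted p under 0.05. Single libraries moved the count of 63 from 1 without control 6, 2 without control 4 and 13 without control 5 to 1076 without miR499 2 and 1986 without miR499 3. It was 22 without control 3, 27 without control 2, 26 without miR499 1 and 100 without miR184 2. It was 2377 with both miR184 3 and miR499 3 left out. Across the 9566 genes the log2 changes of the 2 miRNAs correlated at a Pearson r of 0.114 and a Spearman rho of 0.108. Genes are not independent replicates, the controls were not shared, and without miR499 3 the Pearson r was -0.02. As no gene passed in either comparison, no overlap of calls was computed; at an unadjusted p under 0.05, 22 genes were higher in both, where independent lists would give 17.2, and 10 were lower in both, where they would give 5.05.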

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

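The comparisons with other groupings of the libraries, except that of the 5 libraries left without miR499 3, and the test of the number of distinct molecules were fixed before their results were seen; all other tests given here were chosen only after the result was seen. For the removal of the length and GC trend from the calls, also chosen then, the bounds were set before its own outcome was seen.

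Of 148 values over the 6 control libraries, 4 had a highest or lowest library far from the other 5 for its range. The total of control 6 was 31990355 reads, against 43413665 to 46601798 in the other controls. Cebpa stood at 3.77 RPKM in control 1, against 1.23 to 2.08. Msmo1 stood at 62.6 RPKM in control 5, against 67.1 to 69.7. Relb stood at 6.0 RPKM in control 3, against 2.33 to 3.57. The controls came from 2 tables deposited separately, which can widen the range and hide a library that stands apart. The number of flagged values therefore cannot be set against a chance rate.

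The first pattern is that miR499 3 lay closer to the libraries of the other table than to its own. A constant mixture with reads of such a library is argued against. Genes at least 4-fold higher in the other table's controls lay a median 0.62 of the way there (413 genes) and genes at least 4-fold lower -0.05 (56 genes), a difference of 0.667. A swap with a library of the miR184 table is argued against, as 0 of its libraries correlated more with the miR499 table, and a length and GC bias as the whole cause too, as the spread of the library's deviations was still 1.78 times that of the higher of miR499 1 and 2 with that trend removed (before removal the SD was 0.668, after it 0.501). A single wrong label, a different preparation of this library or a biological difference between cultures may account for it; these stay open and were not tested.

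The second pattern is that miR184 3 listed 13675 genes above 0. Lower depth is argued against, as a library with a lower total listed 3326 genes more, and so is an effect of miR184, as miR184 1 and 2 listed at least 17001, within the range of the controls. Few distinct molecules captured in this library may explain it. Genes with a mean of 5 to 20 reads elsewhere kept 1.06 times the summed reads of the other libraries, relative to the library totals, while 59.5% of them were at 0, against at most 7.12% in any other library of the table.

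The third pattern is that 1681 genes passed without miR499 3, most of them lower with miR499. Scaling is argued against as the whole cause, as 58.6% of the calls were shared in the same direction with median-ratio scaling. The share of lower genes was 79.7% before and 52.4% after. That scaling centres the changes, with a median over all genes of -0.06 before and 0.0052 after, so it draws the share towards balance by construction. Whether scaling caused the excess of lower genes cannot be decided in this way. Reads in genes made up 92.2, 90.9 and 92.1% of the library total in controls 4 to 6, and 88.6 and 89.4% in miR499 1 and 2. As RPKM is scaled to the total, this difference goes in the direction of lower values with miR499. How much of the excess it accounts for was not tested. A trend on transcript length and GC content stays open, as 42.3% of the calls were shared with it removed, between the bounds set beforehand, and the median size of the calls went from 0.40 to 0.31 log2 units (SD 0.16 and 0.18). A batch cannot be told apart from miR499: the descriptions of all 3 controls of that table carry an extra mark that 0 miR499 libraries carry. Of the other groupings of these 5 libraries the highest gave 5 genes, in 10 groupings with the real one included.

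Other groupings of the libraries were counted for each result. With 3 libraries against 3 there are 10 groupings, too few for a share under 0.05. For genes, 10 of the 10 groupings gave as many as the real 0 with miR184 (highest other split 1) and 10 of 10 with miR499 (highest other split 0). For lists, 1 of the 10 splits gave as many as the real 8 with miR184 (highest other 7), and 10 of 10 with miR499, where the real value was 0 and the highest other 4. Where the real value was 0, every grouping gives as many, so these counts of 10 of 10 could not have come out otherwise. For seed sites, 8 of the 10 splits gave a difference as far from 0 as the real one with miR184 (0.0015, highest other 0.0072) and 2 of 10 with miR499 (0.03, highest other 0.04). For the difference between the miRNAs, 6 of 100 drawn splits gave at least 63 genes and the highest gave 194, so chance cannot be excluded. For the correlation, 21 of 100 splits gave a Pearson r as far from 0 as 0.114, with a highest of 0.209, so chance cannot be excluded there either.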

How the results depend on the processing

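Leaving out both replicate 3 libraries, array weights, the joint contrast, removal of transcript length and GC trends from genes, and median-ratio scaling with a library left out were chosen only after the result was seen.

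Where a result moved, the cause was not tested unless stated. With miR184 the gene count of 0 held for the scaling, filter, pseudocount, voom and 12-library alternatives; single libraries left out gave 0 to 2 (2 without control 1), and array weights, which set miR184 3 to 0.118, gave 167 (160 higher, 7 lower). With miR499 the count of 0 held for the same alternatives; single libraries left out gave 0 to 1681 (without miR499 3), median-ratio scaling with miR499 3 left out 1230, and the length and GC trend removed with it left out 931 (377 higher, 554 lower). Array weights were not used for miR499, since miR499 1 received a weight of 174. Of the 8 lists with miR184, 0 passed with an estimated correlation and 0 by fry, and single libraries left out gave 4 (miR184 1) to 9 (control 1), with 5 without control 3. With miR499, 1 list, published miR-184 targets, passed upwards with at least 50 reads in at least 3 libraries (adjusted p = 0.015, camera of limma; adjusted p = 0.887 with an estimated correlation). Single libraries left out gave 0 to 6 (6 without miR499 3, 1 without control 6).

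The replicate block gave 2 genes with miR184 (Gpnmb and Cdkn1c, both higher) and 426 with miR499 (126 higher, 300 lower), and 7 lists with miR499 (0 with an estimated correlation, where the smallest adjusted p was 0.757). The latter fit has 1 residual degree of freedom and its smallest adjusted p, 4.3e-55, is not credible. Same-numbered libraries did not deviate together in every pair, and not every library correlated best with its own number. The block used title numbers with miR184 and description numbers with miR499. By the same numbers, the correlations were 0.06, -0.05 and -0.03 with miR184 by title and 0.20 and -0.35 with miR499 by description. The values with miR184 gave no sign of pairing, which does not exclude it. With miR499 the check cannot decide, because the library that stood apart makes the others of its group deviate alike. There miR499 1 and 2 correlated at 0.20 and 0.19 with control 4, and at -0.22 and -0.35 with control 5. Whether the numbers pair the samples therefore stays open.

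The miR-184-3p site difference of -0.0015 reversed to 0.0346 with 8mers and to 0.0067 with coding sequence sites, and ran from -0.0042 to 0.0020 with single libraries left out. It was -0.0132 with the 3' UTR length and GC trend removed. The miR-499-5p difference of 0.03 had an unadjusted p under 0.05 with 8mers (0.0402), coding sequence sites (0.0483) and at least 50 reads in 3 libraries (0.0343), reversed to -0.0026 with the 3' UTR length and GC trend removed, and ran from 0.0167 to 0.0510 with single libraries left out. The 63 genes whose change differs became 101 with median-ratio size factors, 249 with no filter, 0 in the joint contrast, 2377 with both replicate 3 libraries left out, and 1 to 1986 with single libraries left out. The correlation of 0.114 ran from -0.0240 to 0.151 with single libraries left out and was -0.0219 with both replicate 3 libraries left out; it has no value among genes past the threshold, as there are none. The planned count-model alternatives were not run, since the unit is RPKM. Signs were counted for the genes with the smallest p and the published targets only, 16 genes with miR184 and 19 with miR499. They were kept in all but 8 of 247 uncalled values with miR184 and 11 of 255 with miR499. As the smallest-p genes were picked from these same libraries, a kept sign says little about them. Depth limits genes near 0.0322 to 0.0469 RPKM (3 reads in 2000 bases).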

Other observations

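No test in this part was planned as a comparison of its own; the values are descriptions chosen only after the result was seen.

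Levels of lineage genes differed between libraries within the groups. Mast cell, basophil and eosinophil genes had a mean level of 3.65 to 4.61 log2 units in controls 1 to 3 and 3.82 to 4.61 with miR184. Neutrophil genes ran from 5.25 to 5.80 in these controls and from 5.20 to 5.86 with miR184. Prg2, the eosinophil major basic protein gene, stood at 309 ± 108 RPKM in controls 4 to 6 and 117 ± 93.3 with miR499 (SD, n = 3 each), with overlapping groups. The adult beta-globin gene Hbb-bs stood at 0.0582 ± 0.101 and 4.62 ± 7.69 RPKM, with an SD above the mean in both groups.

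The level of the interferon-stimulated list differed among controls. It was 4.02, 4.56 and 5.35 log2 units in controls 1, 2 and 3, and 3.82 to 4.51 in controls 4 to 6. The estimated correlation between its members was 0.88 with miR184 and 0.53 with miR499.

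Lars2 stood at 81.4 to 92.2 RPKM in controls 4 to 6 and at 206, 96.1 and 378 in miR499 1, 2 and 3. The nuclear noncoding RNA Malat1 stood at 149 RPKM in miR499 3, against 325 to 644 in the other 5 libraries of its table.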
